A study of Mus musculus with 3 samples.

How the data were processed

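Small RNA was sequenced from mouse colonic mucosa in 3 libraries, 1 per group. Per the labels, 1 library came from a healthy mir-10b+/+ mouse (WT), 1 from a mouse with a global deletion of mir-10b labelled diabetic (KO), and 1 from a mir-10b-/- mouse injected with a synthetic miR-10b-5p mimic and labelled rescue (mimic). The labels state total RNA extraction with Trizol, an RNA integrity number above 7.0, about 1 microgram of RNA per library, a TruSeq small RNA kit, and single-end 50-base reads on an Illumina HiSeq instrument.

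The sources used here were the deposited table of values, its header lines and the sample labels. The deposited values are a score, namely normalized miRNA reads per mature miRNA that the authors rounded to whole numbers, per the file headers. The table holds 2 further columns of the unit other, which per the file headers are the differences KO minus WT and mimic minus KO that the authors computed, and they equalled the subtraction with 0 exceptions. The aligner, the counting tool, the miRNA reference and the normalization method are not given in the sources used here. The genome build was mm10 per the submitters' processing notes. The table has 471 rows with 469 different names, since miR-129-3p and miR-125b-3p each occur 2 times. Rows for miR-99a-5p and miR-100-5p hold the same 3 values, as do those for miR-450a-3p and miR-450b-3p. Both rows of each pair were kept in the counts and lists, and an alternative counts each pair once.

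The sums of the normalized reads were 4872446 in WT, 8124898 in KO and 8510085 in mimic, so the columns do not share a total. Values were checked for a common step that would give back whole reads. Of the low values, 16.5% in WT, 22.1% in KO and 21.2% in mimic were whole multiples of the best step within a tolerance of 0.1 of that step, so reads could not be recovered. The sequencing depth is unknown and no counting intervals or detection limits are given. With 1 library per group there is no replicate spread, so no test across samples was run and no p-value is given.

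The choices described in this paragraph were made before the data were examined. Values were used as deposited. Rows with a mean below 10 over the 3 libraries were removed, which left 415 rows and took out 56. Each comparison is a log2 ratio of a pair of libraries after adding a pseudocount of 1, and a row was counted as higher or lower when the ratio was at least 2-fold. The comparisons were KO against WT, mimic against KO and mimic against WT. Among rows at least 2-fold apart between KO and WT, the share whose mimic value lay nearer to WT than to KO on the log2 scale was computed, and the same share was computed with the roles of the libraries exchanged because KO enters both ratios. A planned comparison of that share with unchanged libraries simulated by counting noise needed whole reads and was not run. The named miRNAs are the miR-10 family, the 10 rows with the highest mean, the 10 highest and 10 lowest ratios per comparison among rows with a mean of at least 100, and up to 4 of the most abundant members of each list.

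The 16 lists of miRNAs, also fixed at that stage, were the miR-10/miR-100 family, the miRNAs of the Hox clusters, the miR-200 family, miR-192, miR-194 and miR-215, endocrine cells, barrier-linked miRNAs, smooth muscle, fibroblast and mesenchyme, white blood cells, red blood cells, endothelium, neurons, the let-7 family, the miR-17-92 cluster with its paralogs, metabolic miRNAs, and miRNAs of the imprinted Dlk1-Dio3 cluster, whose list does not hold every annotated member (miR-758, miR-493, miR-1193 and miR-1197 lie in the same span). Both arms of a member count as rows. The miR-10/miR-100 and Hox-cluster lists hold miR-10b itself. For lists with at least 3 measured rows, the median log2 ratio was placed among 10000 random lists of the same size matched on mean level in 10 bins, and a percentile below 2.5 or above 97.5 is called outside the central 95% of random lists. This gave 45 list medians from 15 lists. Rows of a list are not independent replicates, so the percentile describes these 3 libraries only.

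Alternatives planned in advance were scaling each library to the same total, with and without the miR-10b rows, median-of-ratios factors, pseudocounts of 0.1 and 10, no filter, a mean of at least 100, rows of one name summed, and a 1.5-fold limit. Alternatives that keep only the more abundant arm of each miRNA, or count rows with the same 3 values once, were added after seeing the data. The counting of rows was tested on simulated data with Poisson noise around the deposited values. Simulated 4-fold changes were recovered in 100.0% of rows in each comparison, simulated 1.5-fold changes passed the 2-fold limit in 3.4%, 1.7% and 5.1% of rows, and at most 1.7% of unchanged rows passed it. That simulation holds no biological or preparation spread. It also treats the normalized values as reads, although the depth is unknown, so its rates need not hold for these libraries. Loci came from GENCODE M21 on GRCm38, the assembly that mm10 names, and 279 of 301 miRNA base names matched at least 1 annotated locus. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No column of values was left out of the checks, and mature sequences were not analysed here.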

Results

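miRNA levels were measured in colonic mucosa from 3 mouse libraries, 1 each from a wild type labelled healthy (WT), a global mir-10b knockout labelled diabetic (KO), and a mir-10b knockout injected with a miR-10b-5p mimic and labelled rescue (mimic). The study profiled colonic mucosal miRNAs in the presence and absence of mir-10b. Values are normalized reads as deposited, summing to 4872446 in WT, 8124898 in KO and 8510085 in mimic, and the sequencing depth is unknown. The most abundant miRNA was miR-192-5p in WT with 13.5% of the total, miR-21a-5p in KO with 16.7%, and miR-143-3p in mimic with 19.5%. The 10 most abundant rows took 58.2% of the WT total, 66.7% of the KO total and 70.4% of the mimic total. Rows listed at 0 numbered 6 in WT, 39 in KO and 56 in mimic. All comparisons are between single libraries, not between conditions, and no difference below has a replicate check.

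miR-10b-5p, the product of the deleted gene, stood at 18057 normalized reads in WT, 14 in KO and 469 in mimic. The WT value was 1290 times the KO value, and KO held 0.0775% of the WT level. In the mimic library the miRNA was 33.5 times its KO level and reached 2.6% of the WT level. With the pseudocount, the log2 ratios were -10.23 for KO against WT, 4.97 for mimic against KO and -5.26 for mimic against WT. The KO value equalled 0.0278% of that of miR-10a-5p, a close relative in sequence. No row was present for the other arm of miR-10b. Mir10b lies on chromosome 2 at 74726070 to 74726137 of GRCm38, in introns of Hoxd3 and Hoxd4 transcripts.

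Other members of the miR-10 family stayed within a narrower range. miR-10a-5p, from the Hoxb cluster, stood at 42206 in WT, 50417 in KO and 49136 in mimic. miR-99b-5p stood at 23690, 21848 and 22007 in the same order. miR-10a-3p was 788 in WT, 382 in KO and 397 in mimic, a log2 ratio of -1.04 for KO against WT. miR-99a-5p and miR-100-5p, which share all 3 values, were at 14536 in WT, 24780 in KO and 38282 in mimic. miR-100-3p was at 6 in WT and listed at 0 in KO and mimic.

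**Figure D1:**
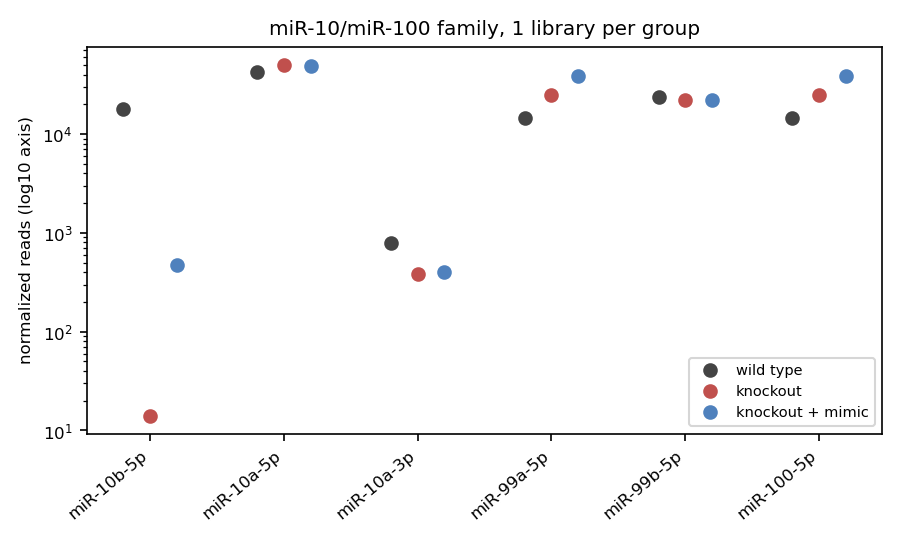
Normalized reads (log10 axis) of miR-10 family members in the WT, KO and mimic libraries, 1 point per library. miR-10b-5p stands at 18057, 14 and 469, while miR-10a-5p lies between 42206 and 50417 in all 3 libraries.

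The comparison of KO with WT sets the mir-10b knockout, labelled diabetic, beside the wild type, labelled healthy, so that genotype and diabetic state differ together. After miR-10b-5p, among rows with a mean of at least 100, the lowest ratios in KO belonged to miR-145b, at 759 in WT and 78 in KO (log2 ratio -3.27), and to miR-98-3p, at 175 and 39 (-2.14). miR-145a-5p, an abundant smooth muscle miRNA, was 261621 in WT and 83319 in KO, 3.14-fold lower. Highest among these rows in KO relative to WT was miR-190a-5p, encoded in an intron of Tln2, at 21 in WT and 304 in KO (log2 ratio 3.79). It was followed by miR-30d-5p, at 7003 and 65605, 9.37-fold higher. miR-21a-5p, widely linked to inflammation and tissue injury, was 319136 in WT and 1360772 in KO, 4.26-fold higher, and miR-148a-3p was 5.59-fold higher at 37461 and 209390.

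Of 415 rows, 88 (21.2%) were at least 2-fold higher in KO than in WT and 40 (9.64%) were at least 2-fold lower, with a 0 in either library for 2 of the higher and 7 of the lower rows. Among other rows with the highest ratios, miR-494-3p reached 2.95, miR-183-3p 2.95, miR-744-5p 2.46, miR-203-3p 2.36, miR-542-3p 2.36 and miR-339-3p 2.29. miR-33-5p, which lies in the Srebf2 gene and acts in cholesterol metabolism, also had a log2 ratio of 2.36, at 164 in WT and 848 in KO. On the lower side were miR-337-3p at -1.84, miR-154-5p at -1.51, miR-329-3p at -1.36, miR-215-3p at -1.33 and miR-26a-3p at -1.21. miR-142a-5p, a miRNA of blood cells, was 31674 in WT and 14200 in KO, a log2 ratio of -1.16. The other arm, miR-142a-3p, went the opposite way, at 1587 and 2753 (0.79).

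In KO against WT the epithelial lists lay inside the central range. The miR-200 family, which maintains epithelial character, had 4 of 9 rows at least 2-fold higher, 0 lower and 5 between, with a median log2 ratio of 0.99 (percentile 96.2 of random lists). Its most abundant member, miR-200a-3p, was 380522 in WT and 754583 in KO, miR-200b-3p was 171853 and 334093, and miR-429-3p was 83919 and 46991. For miR-192, miR-194 and miR-215, typical of gut epithelium, 0 of 6 rows were higher, 1 was lower and 5 lay between, with a median of -0.22 (percentile 10.6) that became 0.72 with only the more abundant arm of each miRNA. miR-194-5p was 85675 in WT and 169274 in KO. miR-192-5p was 656011 in WT and 1081718 in KO, a log2 ratio of 0.72 that became -0.02 when both libraries were scaled to the same total. In the endocrine list 2 of 4 rows were higher and 0 lower, with a median of 0.79 (percentile 86.9), and miR-7a-5p was 3110 and 7580 while miR-375-3p was 93198 and 115315. Barrier-linked miRNAs had 4 of 17 rows higher, 2 lower and 11 between, with a median of -0.11 (percentile 16.6), and miR-29c-3p, a repressor of collagen genes, had a ratio of -1.03.

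Smooth muscle miRNAs went both ways in KO against WT, with 3 of 8 rows at least 2-fold higher, 2 lower and 3 between. Their median log2 ratio of -0.46 was at percentile 1.0, outside the central 95% of random lists and the only list median outside it in this comparison. miR-143-3p was 294225 in WT and 954512 in KO, and miR-1a-3p, a striated muscle miRNA, was 2989 and 7441. Both arms of miR-143 were higher (1.70 for 3p and 1.80 for 5p), whereas miR-145a-5p was lower by the amount given above. Mir143 and Mir145a lie 1301 bases apart on chromosome 18.

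Let-7 rows, known for restraining proliferation and growth, were higher in 6 of 17 cases, lower in 1 and between in 10, with a median of 0.68 (percentile 92.9) that became -0.06 with equal totals and 1.20 (percentile 98.5, outside the central range) with only the more abundant arm. let-7g-5p was 50354 in WT and 124550 in KO, and let-7c-5p was 30393 and 79683. The miR-17-92 clusters had 5 of 19 rows higher, 0 lower and 14 between, with a median of 0.17 (percentile 59.5) and -0.56 with equal totals. Metabolic miRNAs had 4 of 20 rows higher, 3 lower and 13 between, with a median of -0.26 (percentile 3.2), among them miR-27b-3p at 299991 and 277980 and miR-378a-3p at 211958 and 153738. The imprinted Dlk1-Dio3 cluster had 11 of 49 rows higher, 4 lower and 34 between, with a median of 0.22 (percentile 92.8) and -0.51 with equal totals.

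The remaining lists, most of them markers of other cell types, lay inside the central range in KO against WT where a percentile was computed. Fibroblast and mesenchyme miRNAs had 0 of 7 rows higher and 0 lower, with a median of 0.22 (percentile 48.3) and -0.52 with equal totals. White blood cell miRNAs had 2 of 8 rows higher, miR-146a-5p at 1.14 and miR-146b-5p at 1.54, and 1 lower, with a median of -0.05 (percentile 28.5) against a mean of 0.08. Red blood cell miRNAs had 2 of 4 higher and 0 lower, with a median of 0.60 (percentile 80.8) and -0.13 with equal totals. Neuronal miRNAs had 0 of 11 higher and 1 lower, with a median of -0.19 (percentile 22.2). The miR-10/miR-100 family had 0 of 8 higher and 2 lower, miR-10b-5p itself and miR-10a-3p, with a median of 0.19 (percentile 39.7) and -0.53 with equal totals. The family mean of -1.15 includes the ratio of -10.23 of miR-10b-5p. With its identical miR-99a-5p and miR-100-5p rows counted once, the family median was 0.18 in KO against WT, 0.01 in mimic against KO and -0.11 in mimic against WT. The Hox-cluster miRNAs had 0 of 7 higher and 2 lower, again miR-10b-5p and miR-10a-3p, with a median of -0.14 (percentile 18.5). Of the endothelial miRNAs 2 rows were measured, and miR-126a-3p was 38616 in WT, 53124 in KO and 82351 in mimic, while miR-126a-5p was 21218, 24824 and 40238.

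Scaling each library to the same total added -0.74 to every log2 ratio of KO against WT, -0.07 for mimic against KO and -0.80 for mimic against WT. Median-of-ratios factors added -0.15, 0.29 and 0.14. In KO against WT the split of 88 higher and 40 lower rows (68.8% higher) became 30 and 141 (17.5%) with equal totals and 71 and 61 (53.8%) with median-of-ratios factors, so the direction of the split depended on the scaling.

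**Figure D2:**
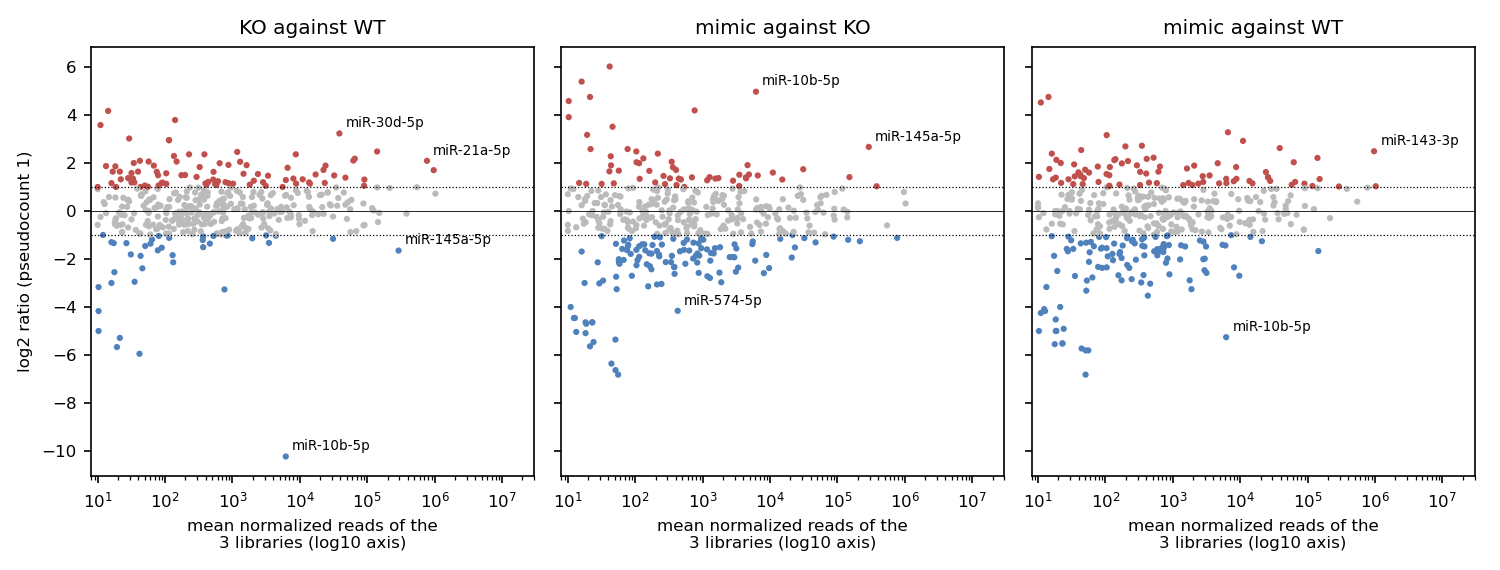
Log2 ratio (pseudocount 1) against the mean normalized reads of the 3 libraries (log10 axis) for 415 rows in each comparison, with dotted lines at 2-fold, red points at least 2-fold higher and blue points at least 2-fold lower. miR-10b-5p stands at -10.23, 4.97 and -5.26, and rows listed at 0 in a library take a ratio set by the pseudocount.

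The comparison of mimic with KO sets a knockout library with the injected miR-10b-5p mimic beside a separate knockout library without it. The labels name no control injection, so mimic, injection and sample differ together. The label of KO is diabetic and that of mimic is rescue. After miR-10b-5p itself, the highest ratio among rows with a mean of at least 100 belonged to miR-145b, at 78 in KO and 1443 in mimic (log2 ratio 4.19). miR-145a-5p was 83319 in KO and 529831 in mimic, 6.36-fold higher. miR-574-5p, encoded in an intron of Fam114a1, had the lowest ratio of these rows, at 751 in KO and 41 in mimic, 17.9-fold lower. miR-127-3p, the most abundant member of the Dlk1-Dio3 cluster, was 12073 in KO and 2006 in mimic, 6.02-fold lower. miR-21a-5p was 1360772 in KO and 626341 in mimic, a log2 ratio of -1.12.

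Of 415 rows, 55 (13.3%) were at least 2-fold higher in mimic than in KO and 117 (28.2%) were at least 2-fold lower, with a 0 in either library for 6 and 16 of them. Others with high ratios were miR-133a-5p at 2.48, miR-708-3p at 2.39, miR-98-3p at 2.19, miR-147-5p at 2.05, miR-488-3p at 2.03, miR-181b-1-3p at 1.99 and miR-374b-5p at 1.91. Others with low ratios were miR-672-5p at -3.14, miR-1198-5p at -3.06, miR-382-5p at -3.04, miR-541-5p at -2.97, miR-423-5p at -2.79, miR-744-5p at -2.72, miR-33-5p at -2.62 and miR-455-3p at -2.58.

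Smooth muscle miRNAs were higher in mimic than in KO in 6 of 8 rows, lower in 0 and between in 2, with a median log2 ratio of 1.54 at percentile 100. miR-1a-3p was 7441 in KO and 22584 in mimic, miR-143-3p was 954512 and 1655929, miR-145a-3p was 9886 and 24569, and miR-133b-3p was 1286 and 1726. The Dlk1-Dio3 list, of which 38 annotated loci lie between 109571990 and 109743795 on chromosome 12, was lower in 28 of 49 rows, higher in 0 and between in 21, with a median of -1.39 at percentile 0.0. miR-136-3p was 2310 in KO and 2047 in mimic, and miR-300-3p was 2208 and 1356. These were the list medians outside the central 95% in this comparison, and both kept their sign under equal totals (1.48 and -1.45) and median-of-ratios factors (1.83 and -1.10).

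Epithelial lists lay inside the central range in mimic against KO. The miR-200 family had 0 of 9 rows higher, 3 lower and 6 between, with a median of -0.15 (percentile 47.2) that became 0.13 with median-of-ratios factors, and miR-200b-3p was 334093 in KO and 139362 in mimic. For miR-192, miR-194 and miR-215, 1 of 6 rows was higher and 0 lower, with a median of 0.54 (percentile 92.1), and miR-215-5p was 92654 and 175976. In the endocrine list 0 of 4 rows were higher and 1 was lower, with a median of 0.34 (percentile 84.3), and miR-375-3p was 115315 and 54757. Barrier-linked miRNAs had 6 of 17 rows higher, 3 lower and 8 between, with a median of 0.39 (percentile 96.4). Among them miR-29a-3p was 95703 in KO and 255114 in mimic, 2.67-fold higher, and miR-34c-3p, listed at 0 in KO, was at 14 in mimic.

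Of the remaining lists in mimic against KO, metabolic miRNAs had 7 of 20 rows higher, 5 lower and 8 between, with a median of 0.21 (percentile 92.1). Among them miR-27b-3p was 277980 in KO and 567023 in mimic and miR-378a-3p was 153738 and 66829. The miR-17-92 clusters had 0 of 19 higher, 7 lower and 12 between, with a median of -0.75 (percentile 10.9), and miR-93-5p was 17740 and 7958. The let-7 family had 3 of 17 higher, 5 lower and 9 between, with a median of -0.35 (percentile 26.3), and let-7d-3p was 11921 and 2284. Fibroblast and mesenchyme miRNAs had 0 of 7 higher and 2 lower, with a median of -0.89 (percentile 14.1), and miR-214-3p was 2211 and 371. White blood cell miRNAs had 1 of 8 higher, miR-142a-5p at 14200 and 47347, and 1 lower, miR-342-3p at 3074 and 1174, with a median of -0.59 (percentile 20.7). miR-142a-3p was 2753 in KO and 1804 in mimic, a log2 ratio of -0.61.

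Red blood cell miRNAs had 1 of 4 higher in mimic than in KO, miR-451a at 849 and 2164, and 0 lower, with a median of 0.26 (percentile 82.6). Neuronal miRNAs had 2 of 11 higher and 1 lower, with a median of -0.04 (percentile 82.3), a mean of 0.04, and a median of 0.25 with median-of-ratios factors. The miR-10/miR-100 family had 1 of 8 higher, miR-10b-5p itself, and 1 lower, with a median of 0.03 (percentile 73.3) and -0.03 with equal totals. With only the more abundant arm the family median was 0.63 (percentile 99.3), the value of the identical miR-99a-5p and miR-100-5p rows. The Hox-cluster miRNAs had 1 of 7 higher, again miR-10b-5p, and 2 lower, with a median of -0.04 (percentile 71.2) and 0.25 with median-of-ratios factors. Their mean of 0.31 includes the ratio of 4.97 of miR-10b-5p. The share of higher rows among those at least 2-fold apart was 32.0% as deposited and 43.5% with median-of-ratios factors (77 higher and 100 lower).

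**Figure D3:**
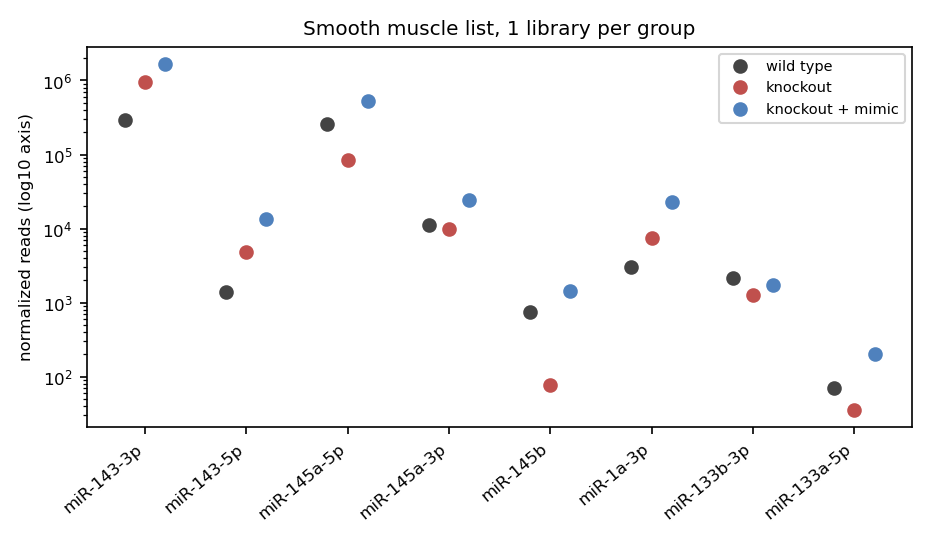
Normalized reads (log10 axis) of the 8 smooth muscle rows in the WT, KO and mimic libraries, 1 point per library. The mimic value is above the KO value for each row, and in KO miR-143-3p lies above WT while miR-145a-5p lies below it.

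The comparison of mimic with WT asks how far the treated knockout library lay from the wild type. Among rows with a mean of at least 100, both arms of miR-143 had high ratios in mimic, with miR-143-5p at 1387 in WT and 13503 in mimic, 9.73-fold higher, and miR-143-3p at 294225 and 1655929, 5.63-fold higher. miR-1a-3p was 2989 and 22584, 7.55-fold higher. After miR-10b-5p, the lowest ratios of these rows belonged to miR-574-5p, at 485 in WT and 41 in mimic (log2 ratio -3.53), and to miR-541-5p of the Dlk1-Dio3 cluster, at 2949 and 306 (-3.26). miR-214-3p, a mesenchymal miRNA, was 2749 and 371, 7.39-fold lower.

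Of 415 rows, 82 (19.8%) were at least 2-fold higher in mimic than in WT and 107 (25.8%) were at least 2-fold lower, with a 0 in either library for 2 and 17 of them. Other high ratios were those of miR-488-3p at 3.16, miR-147-5p at 2.72, miR-340-3p at 2.69, miR-30d-5p at 2.62, miR-30d-3p at 2.22, miR-148a-3p at 2.21 and miR-27a-5p at 2.17. Other low ratios were those of miR-329-3p at -3.03, miR-495-3p at -2.98, miR-674-5p at -2.89, miR-382-5p at -2.84, let-7d-3p at -2.70 and miR-672-5p at -2.68. The share of higher rows among those at least 2-fold apart was 43.4% as deposited, 13.4% with equal totals (7.23% of all rows higher and 46.7% lower) and 50.0% with median-of-ratios factors (95 and 95).

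Smooth muscle miRNAs were higher in mimic than in WT in 6 of 8 rows and lower in 0, with a median of 1.34 at percentile 100 and 0.54 with equal totals. The Dlk1-Dio3 cluster was higher in 2 of 49 rows, lower in 24 and between in 23, with a median of -0.94 at percentile 0.1. Barrier-linked miRNAs were higher in 4 of 17 rows, lower in 2 and between in 11, with a median of 0.66 at percentile 97.7 that became -0.13 with equal totals. Within that list miR-29a-3p was 101418 in WT and 255114 in mimic, and miR-21a-5p was 319136 and 626341. Those 3 lists lay outside the central 95% of random lists in mimic against WT. Over the 3 comparisons 6 of 45 list medians did, where 2.2 would be expected if the medians were independent and list rows behaved as random rows. They are not independent, since the comparisons share libraries and some lists share members. Smooth muscle was outside in all 3 comparisons and Dlk1-Dio3 in both that hold the mimic library, so no excess over chance can be read from the number.

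The miR-200 family had 2 of 9 rows higher in mimic than in WT and 0 lower, with a median of -0.16 (percentile 21.6) and a mean of 0.22. For miR-192, miR-194 and miR-215, 2 of 6 rows were higher and 0 lower, with a median of 0.39 (percentile 69.0) and -0.41 with equal totals, and miR-192-5p was 656011 and 1341381. The endocrine list had 2 of 4 higher and 0 lower, with a median of 0.67 (percentile 82.7), -0.13 with equal totals and 1.34, just outside the central range, with only the more abundant arm. The let-7 family had 1 of 17 higher and 2 lower, with a median of 0.06 (percentile 58.7), a mean of -0.12, and a median of -0.74 with equal totals. Metabolic miRNAs had 4 of 20 higher and 5 lower, with a median of 0.29 (percentile 88.2), a mean of -0.07, and a median of -0.52 with equal totals. The miR-17-92 clusters had 1 of 19 higher and 4 lower, with a median of -0.46 (percentile 18.3).

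Hox-cluster miRNAs had 0 of 7 rows higher in mimic than in WT and 4 lower, miR-10b-5p among them, with a median of -1.01 (percentile 2.8). It became -1.24 (percentile 2.1) with only the more abundant arm, and miR-196a-5p was 1894 and 680. The miR-10/miR-100 family had 2 of 8 rows higher, the identical miR-99a-5p and miR-100-5p rows, and 1 lower, miR-10b-5p itself. Its median was -0.05 (percentile 32.6) and became 0.08 with median-of-ratios factors. Fibroblast and mesenchyme miRNAs had 0 of 7 higher and 2 lower, with a median of -0.83 (percentile 3.6). White blood cell miRNAs had 1 of 8 higher and 2 lower, with a median of 0.26 (percentile 76.3), a mean of -0.17, and a median of -0.54 with equal totals. Red blood cell miRNAs had 2 of 4 higher and 0 lower, with a median of 0.79 (percentile 94.2) and -0.01 with equal totals. Neuronal miRNAs had 1 of 11 higher and 1 lower, with a median of -0.17 (percentile 55.2).

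**Figure D4:**
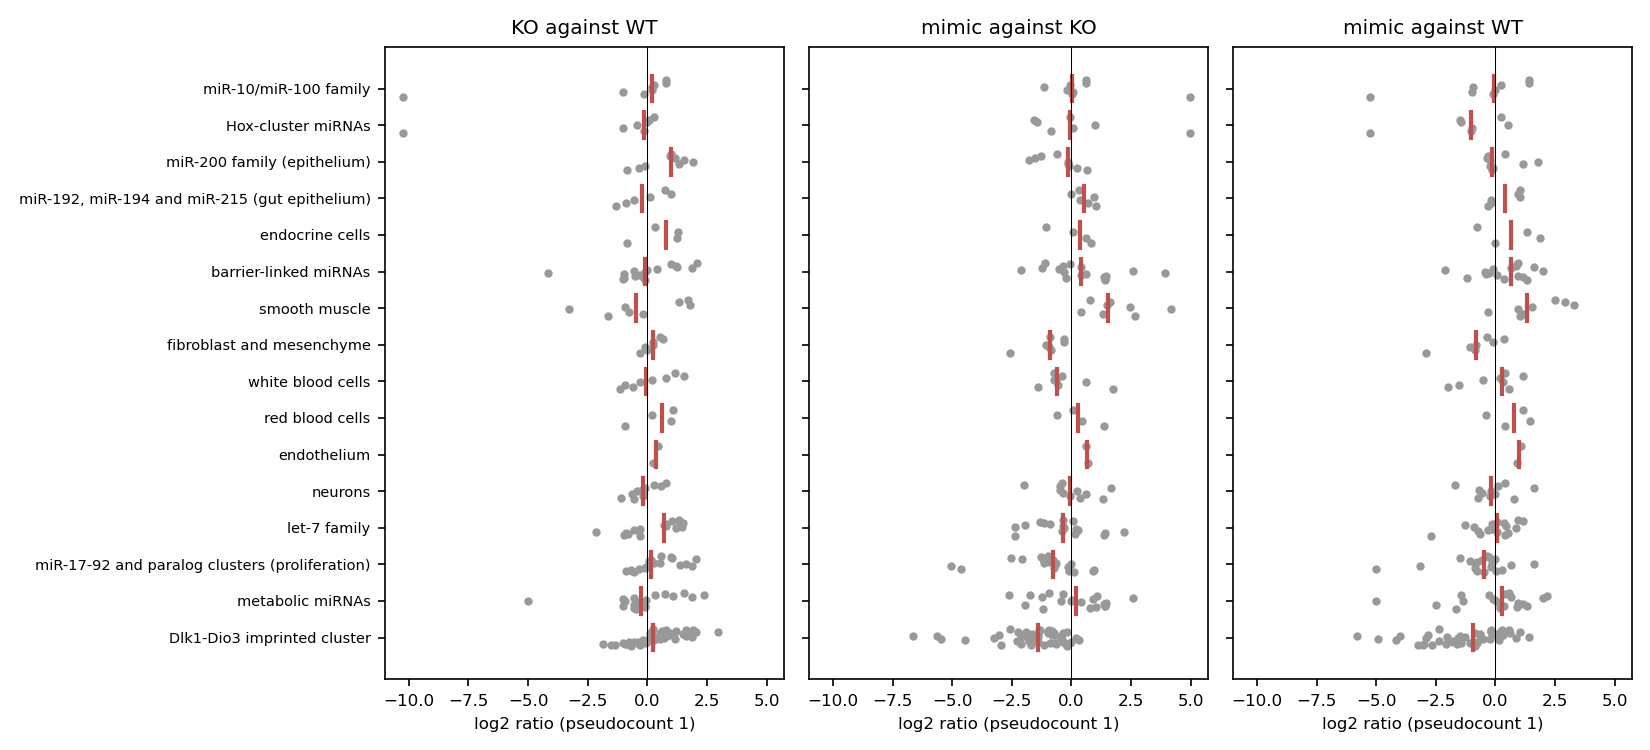
Log2 ratios (pseudocount 1) of the measured rows of 16 miRNA lists in each comparison, 1 grey point per row, with the list median as a red bar. The smooth muscle median stands at -0.46, 1.54 and 1.34 and the Dlk1-Dio3 median at 0.22, -1.39 and -0.94, and rows listed at 0 in a library take a ratio set by the pseudocount.

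Whether the mimic library lay nearer to WT or to KO was asked for the rows that separated KO from WT. Of the 128 rows at least 2-fold apart between KO and WT, 58 had a mimic value nearer to WT than to KO, which is 45.3% (exact 95% interval 36.5 to 54.3 over rows, which are not independent). Of the 88 rows higher in KO, 40 were nearer to WT with the mimic and 36 lay within 2-fold of WT, miR-33-5p among them at 164 in WT, 848 in KO and 137 in mimic. Of the 40 rows lower in KO, 18 were nearer to WT and 16 lay within 2-fold of it, such as miR-98-3p at 175, 39 and 182. The more abundant arm of that hairpin, miR-98-5p, was higher in KO and stayed nearer to KO, at 1662, 3821 and 3057. miR-30d-5p, at 7003, 65605 and 43133, and miR-148a-3p, at 37461, 209390 and 173201, stayed nearer to KO. With the roles exchanged, 118 of 172 rows apart between mimic and KO had a WT value nearer to KO than to mimic (68.6%, 61.1 to 75.5), and 118 of 189 rows apart between mimic and WT had a KO value nearer to WT than to mimic (62.4%, 55.1 to 69.4). Without any order among the libraries the share would be 50% only if the libraries had the same spread. That was not tested, so 50% is not an established reference for these shares. The return share was 31.6% with equal totals and 50.7% of 223 rows with a limit of 1.5-fold.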

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

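The alternatives with only the more abundant arm and with identical rows counted once were chosen after the result was seen, and the others were planned. With each library scaled to the same total, the log2 ratios of miR-10b-5p were -10.96, 4.89 and -6.07 for KO against WT, mimic against KO and mimic against WT, 7.23% of rows were higher and 34.0% lower in KO against WT and 7.23% and 46.7% in mimic against WT (21.2%, 9.64%, 19.8% and 25.8% as deposited), and the median of barrier-linked miRNAs in mimic against WT reversed to -0.13. The share of rows nearer to WT with the mimic was then 31.6%, and leaving miR-10b out of the total gave 31.0% and otherwise the same values. These shifts follow from the construction, since the deposited totals differ. Median-of-ratios factors gave -10.37, 5.25 and -5.13 for miR-10b-5p and 14.7% of rows lower in KO against WT. The ratios of miR-10b-5p were -10.32, 5.06 and -5.27 with a pseudocount of 0.1 and -9.56, 4.32 and -5.24 with 10, so its direction held in each of these 5 alternatives. Without the filter 15.9% of rows were lower in KO against WT. With a mean of at least 100 19.2% were higher and 5.96% lower in KO against WT and 22.2% lower in mimic against WT, among fewer rows. At 1.5-fold 33.0% were higher and 20.7% lower in KO against WT and 22.4% higher in mimic against KO, and the share nearer to WT with the mimic went from 45.3% to the other side of 50% at 50.7%, for which the cause was not tested. With only the more abundant arm of each miRNA, 7.84% of rows were lower in KO against WT, 8.96% higher in mimic against KO and 17.5% higher in mimic against WT. In that setting 10 list medians lay outside the central range in place of 6. The added ones were let-7 in KO against WT, miR-10/miR-100 in mimic against KO, and Hox-cluster and endocrine in mimic against WT. The added miR-10/miR-100 median of 0.63 was the value of the identical miR-99a-5p and miR-100-5p rows, and that list holds miR-10b-5p itself. The number of list medians outside was 9 without the filter, and 5 with a pseudocount of 10 or a mean of at least 100. Identical rows counted once changed the sign of 0 list medians. Sign changes affected 14 of 45 list medians and 40 of 294 ratios of named miRNAs with equal totals, 4 of 45 and 18 of 294 with median-of-ratios factors, and 0 with either pseudocount. No replicate spread exists against which to judge these movements, and the unknown depth limits what low values can show.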

Other observations

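All tests in this part were chosen after the result was seen, and the families named in the next paragraph were picked after their values were seen. The 5p arms of the miR-30 family were higher in KO than in WT in 5 of 5 members, with a median log2 ratio of 2.10 (1.71 to 3.23), against 1 of 5 for the 3p arms (median -0.05, and lower still with equal totals). miR-30e-5p was 24946 in WT and 113295 in KO, and miR-30a-5p was 19934 and 85382. The 5p arms of let-7 had a median of 1.18 (0.68 to 1.48), which stays above 0 after the shift of -0.74 from equal totals although its lowest member does not, and the 3p arms had a median of -0.55 (-0.96 to -0.31). In mimic against KO the 3p arms of miR-29, whose targets include collagen genes, were higher in 3 of 3 members by 1.37 to 1.41. The 5p arms of miR-29 went both ways there, with 1 of 3 at least 2-fold higher and 1 lower (-1.23 to 1.46). Also computed were miR-23, with 0 of 2 3p rows at least 2-fold apart in mimic against KO, and miR-27, with 1 of 2 rows higher in each arm.

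The 50 most abundant rows had a median log2 ratio of 0.50 in KO against WT, with 14 rows at least 2-fold higher and 2 lower, while the other 365 rows had a median of 0.08. In mimic against WT these medians were 0.49 and -0.21. With equal totals each of these medians falls below 0, as the shifts of -0.74 and -0.80 are larger. Rows were ranked by the mean of the 3 libraries, which favours rows raised in KO or mimic for the top 50. The higher medians of those rows may therefore be partly built in.

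In KO against WT the log2 ratios of the 5p and 3p arms of the same hairpin correlated at -0.02 (Pearson) and 0.07 (Spearman) over 143 pairs, and at 0.22 (Pearson, bootstrap -0.07 to 0.48) over the 41 pairs with both arms at a mean of at least 500. The same correlations were 0.39, 0.42 and 0.38 in mimic against KO, and 0.35, 0.31 and 0.62 (bootstrap 0.37 to 0.79) in mimic against WT, so the low correlation was not shared by both comparisons that hold the WT library. Counting noise of low values may lower that correlation, which the value of 0.22 leaves open. The shift of 5p over 3p was not confined to low values, since it was 0.52 (bootstrap 0.12 to 0.92) over the abundant pairs. Over the 53 pairs whose rarer arm had a mean under 100 it was 0.21. The 5p ratio was the higher in 93 of 143 pairs. Whether the shift goes with the 5p arm or with the more abundant arm of a pair was not tested. A preparation difference of the WT library alone would shift 5p minus 3p in both of those comparisons and not in mimic against KO, and the medians were 0.59 (bootstrap 0.16 to 0.82) in KO against WT, 0.40 (-0.12 to 0.63) in mimic against WT and -0.11 (-0.35 to 0.15) in mimic against KO over all pairs, and 0.52 (0.12 to 0.92), 0.26 (-0.13 to 0.55) and -0.24 (-0.65 to 0.17) over the abundant pairs. These intervals leave it open, and with 1 WT library it cannot be told apart from genotype or from the labelled diabetic state, neither of which was tested.

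Rows of the smooth muscle list differed between the libraries, with 6 of 8 rows at least 2-fold higher in mimic than in KO, led by miR-145b (4.19), miR-145a-5p (2.67) and miR-133a-5p (2.48). The list is not specific to smooth muscle, since it also holds the striated muscle miRNA miR-1a-3p, and its rows are not independent. Less smooth muscle in KO than in WT stays open, because the log2 ratio of miR-143-3p in KO against WT exceeded that of miR-145a-5p, from the same cluster, by 3.35 but that of miR-145a-3p by 1.86, against an SD of 1.18 between the arms of the 41 hairpins with both arms at a mean of at least 500. The list did not fall together in KO, with 3 of 8 rows at least 2-fold higher, 2 lower and 3 between. Both arms of miR-143 were among the higher rows (1.70 and 1.80), while the list median was -0.46. More smooth muscle tissue in the mimic sample than in the KO sample may contribute, but the gaps of miR-145a arms over miR-143 arms there ran from -0.17 to 1.87, which neither excludes nor supports it. With 1 library each, these cannot be told apart from effects of genotype, of the labelled diabetic state, or of the mimic or its injection. A preparation difference between libraries and a difference between animals stay open as well, and none of these was tested.

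The Dlk1-Dio3 cluster was lower in mimic than in KO. Lower depth of the mimic library is argued against as the only source, because the 10 rows of the cluster with a mean of at least 500 had a median of -0.95 (bootstrap -1.96 to -0.70) while the 188 other rows as abundant had -0.23. Of those 10 rows 4 were at least 2-fold lower and 0 higher, against 28 of 49 lower in the whole list. Loss of low values may add to the list median of -1.39, as members such as miR-485-3p and miR-667-3p were listed at 0 in mimic. Rows of one cluster are not independent, so the bootstrap interval describes these rows only. Fewer fibroblasts in the mimic sample could contribute, since the fibroblast and mesenchyme list had a median of -0.89 (bootstrap -1.08 to -0.31, with all rows at -0.31), but its 7 rows are too few. Falls were not confined to the cluster, as 117 of all 415 rows were at least 2-fold lower in mimic than in KO. Fewer fibroblasts cannot be told apart from an effect of the mimic or its injection, a preparation difference of the mimic library, or a difference between animals, all untested.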
